A study of Mus musculus with 82 samples.

How the data were processed

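Liver RNA of BXD recombinant inbred mice and of their parental strains, C57BL/6J (B6) and DBA/2J (D2), was measured on 82 two-colour arrays of 21936 probes each. On 74 arrays liver RNA was set against a mix of RNA from B6 embryos of day 17.5, per the labels. On 6 arrays B6 liver was set directly against D2 liver, and on 2 arrays so were RNAs labelled as enriched. The series description names 18 BXD strains, males and 3 unfasted mice of 10 to 20 weeks per strain, while the labels of the arrays hold 17 BXD strains and both sexes. Whether each RNA was a pool of mice is not given in the sources used here.

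The deposited values are 1 log ratio per probe and array, with no unit in the labels. They were read as log10 ratios, because 94 deposited values sit exactly at a bound of 2 on either side of 0, which on the log10 scale is a 100-fold range, and they were multiplied to log2. The base is not stated, so every log2 ratio and fold below rests on that reading. No value was missing and 2388 values were exactly 0. Array medians lay near 0 before any step here, so centring upstream is likely. The scanner, the software and the normalization are not given in the sources used here. Signal intensity and background were not analysed here.

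The dyes do not give the direction of a ratio, since both channels carry the label cy3. Forward and swapped arrays of the same RNA correlated between -0.895 and -0.556 across probes for the 32 pairs against the embryo mix, so swapped values were deposited unturned and were multiplied by -1. A fixed list of 16 adult hepatocyte genes then had a higher median than a fixed list of 15 embryonic genes on 74 of 74 arrays when the value was read as channel 2 over channel 1 (lowest hepatocyte median 2.66, highest embryonic median -0.84, log2). That reading is likely and was used for all arrays. Forward and swapped B6 and D2 arrays correlated at only -0.0187 (labelled male) and 0.133 (labelled female) after turning, so there the reading rests on the dye effect, the component shared by arrays of the same orientation. It correlated at 0.762 (labelled male pair) and 0.673 (labelled female pair) with that of the BXD arrays across features, and features are not independent replicates.

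Gene names came from the platform annotation, which gave 3290 probes 1 symbol and 4 probes several, and from a mouse RefSeq gene table (GRCm38.p6, used only for names and for which genes neighbour each other), through which another 170 probes were named by accession. A total of 18476 probes had no name here, and they were tested and counted but not named. Probes of the same symbol were averaged for 18 genes, which left 21915 features, of which 3439 were named. Such probes did not always move together: the lowest correlation over 34 values ran from -0.297 for Pth1r to 0.990 for Btg2, and none of these 18 genes is named for its value below.

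Arrays of a strain and sex were averaged within each orientation and then across orientations. Of the 17 strains, 13 had both orientations in both sexes, and BXD strains 8, 9, 14 and 27 had forward arrays only. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) with Benjamini-Hochberg adjustment at 0.05 over all features. Liver was tested against the embryo mix on 13 strain means, with an absolute log2 ratio of at least 1 also required. The mix is 1 reference, so its own spread is outside the test. Females were tested against males on 34 values with strain as a block, since each strain gave both sexes. Strain differences were tested by a moderated F on 26 values of 13 strains with sex as a term. B6 was tested against D2 on 4 values, 1 per sex and replicate number, and the difference between sexes by a sex term on the same values. The overlap of the B6 and D2 calls with the strain calls was tested by Fisher's exact test, and strain identity between the sexes by 100000 permutations of strain labels, 1-sided for larger values.

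Before the data were examined, 27 gene lists were fixed: sex-biased, X- and Y-linked genes, liver pathways, markers of other cell types, and neighbouring organs. Lists with at least 5 measured members, 23 in all, were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Strain differences used Fisher's exact test. Genes named in the text were, for the comparisons with a direction, the 12 largest called changes per direction whose sign held in at least 90% of strains (in all 4 values for B6 against D2), and for strain differences the 20 largest F values, besides members of the lists. Symbols that are clone names were passed over, and the results of some genes that met these rules are not reported here.

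Alternatives covered centring, scaling, quantile normalization, single probes, trend and robust settings, orientation, sex, replicate 1, other strain sets, strains or values left out in turn, a dye term, a replicate block and the enriched arrays. Others were added after seeing the data: runs of consecutively deposited arrays as a term, a pair of swapped arrays exchanged, strains left out, a dye effect subtracted, and values labelled female left out. The runs are inferred from the order of deposit and no hybridisation date was available.

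The fits were tested on simulated data with 21915 features. Noise was drawn independently for each feature and value from a normal distribution with the SD of that feature. It held no run effect, dye effect or correlation between genes, so the results below do not give the error rates on the real arrays. Of 100 features changed by 0.5 and 100 by 1 (log2), 84% and 99% were recovered in the female against male fit with 14 false calls. In the strain fit the effect of each strain was drawn from a normal distribution with an SD of 0.5 or 1 (log2). Of 100 features of each SD, 84% and 97% were recovered there, with 4 false calls. Of 100 changed by 1 and 100 by 2 in the B6 against D2 fit of 4 values, 74% and 95% were recovered with 7 false calls. In the liver against embryo fit all of 100 features changed by 1.5 and all of 100 changed by 3 were recovered. Smaller changes were not simulated for that fit. Camera gave p = 5.68e-60 for 20 genes shifted by 0.5 and p = 0.295 for 20 unshifted genes.

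One BXD11 female array was left out of the main fits because its title and its channel labels give opposite orientations. The enriched arrays had no second orientation and what was enriched is not stated, so they were set beside the B6 against D2 result and entered fits only as alternatives.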

Results

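Liver transcripts were measured in 17 BXD strains, which carry mosaics of the B6 and D2 genomes. There were 32 arrays of males and 40 of females against the embryo mix, 2 of B6 males against that mix, 6 of B6 against D2 liver, and 2 of enriched B6 against enriched D2 RNA. The spread of the log2 ratios within an array was 0.72 to 1.10 (SD over probes) for BXD males, 0.69 to 1.12 for BXD females, and 0.28 to 0.64 for the direct B6 and D2 arrays, where liver met liver. Array medians lay between 0.01 and 0.12 for BXD females. The tested features numbered 21915, of which 3439 had a gene name.

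Adult liver was set apart from the embryo mix by enzymes and secreted proteins of hepatocytes. Ugt2b5, which glucuronidates steroids and drugs, was 32.6-fold higher in liver (log2 5.03 ± 0.21 SD, n = 13 strains), and the steroid hydroxylase Cyp2a4 was 27.7-fold higher (log2 4.79 ± 0.34). The complement regulator C4bp (4.73 ± 0.20), the methyltransferase Gnmt (4.70 ± 0.19), the lipoprotein-bound esterase Pon1 (4.67 ± 0.15), the lectin Mbl2 (4.64 ± 0.19) and the bile acid conjugating enzyme Baat (4.46 ± 0.17) followed. Lower in liver were genes of other tissues: the matrix protein Postn stood at -5.47 ± 0.22, the lung surfactant gene Sftpc at -5.25 ± 0.12, the troponin Tnnc2 at -5.14 ± 0.13 and the imprinted fetal gene Dlk1 at -4.62 ± 0.24. Each of these 11 genes had its sign in 13 of 13 strains.

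Hsd11b1, which regenerates glucocorticoids (log2 4.41 ± 0.17), Agxt, which detoxifies glyoxylate (4.34 ± 0.12), the carboxylesterase Ces1c (4.50 ± 0.26), Rida (4.59 ± 0.22) and the retinol dehydrogenase Rdh7 (4.31 ± 0.11) complete the 12 largest named increases. On the lower side stood Itm2a (-4.47 ± 0.17), the fibrillar collagen Col5a1 (-4.23 ± 0.11), Rtn2 (-4.18 ± 0.15), the bone sialoprotein Ibsp (-4.10 ± 0.15), Anxa1 (-4.07 ± 0.21), Bex3 (-4.01 ± 0.16), Ppic (-4.01 ± 0.08) and Calm4 (-4.00 ± 0.12). On the B6 male pair of arrays, which was not part of the fit and shared the embryo mix, Ugt2b5 read 4.68, Baat 4.25, Postn -5.46 and Sftpc -4.98. Agxt at 3.45, Mbl2 at 3.87 and Hsd11b1 at 3.81 lay farther from their strain means. Of the 24 named genes 8 lay within the SD across strains there and 16 outside it. The strain means and their SD are over both sexes, while that pair is of males only, so the measures are unlike.

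Of the 16 measured adult hepatocyte genes 15 were higher in liver, among them Mat1a, the S-adenosylmethionine synthase (4.25), the gluconeogenic enzyme Pck1 (3.78) and the urea cycle enzymes Otc (3.36) and Arg1 (2.73). Ahsg, at 0.16, stayed under the size threshold (camera adjusted p = 4.64e-07, and adjusted p = 0.0399 with an estimated correlation). All 9 bile acid genes were higher, with the fatty acid and bile acid CoA ligase Slc27a5 at 3.57, the bile salt export pump Abcb11 at 3.15 and the phospholipid pump Abcb4 at 2.78 (camera adjusted p = 9.72e-05, and adjusted p = 0.0112 with an estimated correlation). Embryonic and fetal genes were lower in 9 of 15 cases, with Cdkn1c, a brake on the cell cycle, at -3.61, the heparan sulphate proteoglycan Gpc3 at -3.32 and the fetal growth factor Igf2 at -3.25. The embryonic globins Hba-x at -0.54 and Hbb-y at -0.70 did not reach the threshold (camera adjusted p = 4.81e-06, and adjusted p = 0.0112 with an estimated correlation). These 3 list calls held with an estimated correlation. The direction of the hepatocyte and embryonic results is not a finding, since the sign of the ratios was read from these same lists.

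For the remaining 13 lists called by camera the estimated correlation removed the call. Drug and steroid metabolism genes were higher in 15 of 18 (Aldh1a1 4.22, Nnmt 3.61, Fmo5 3.25), and acute-phase genes in 8 of 9 (Fgl1 4.09, Orm1 3.94, Cp 3.07), each with adjusted p = 0.0570 with an estimated correlation. Cell division genes were lower in 9 of 13 (the chromatin protein Hmgb2 -3.57, the survivin gene Birc5 -3.06, the ribonucleotide reductase subunit Rrm2 -2.74), each with adjusted p = 0.0570 with an estimated correlation. Red blood cell genes were lower in 3 of 6 (Hba-a1 and Ermap among them), and female-biased liver genes higher in 7 and lower in 1 of 13 (Lpl, -2.45), both again with adjusted p = 0.0570 with an estimated correlation. Stellate cell and fibroblast markers were lower in 3 of 6 (adjusted p = 0.0588 with an estimated correlation), parental variant genes higher in 2 of 7 (0.112 likewise), and kidney, fat and muscle genes lower in 3 of 6 (0.146). Male-biased liver genes were higher in 5 of 7 and respiratory chain genes in 1 of 10 (both 0.150), ribosomal protein genes lower in 3 of 9 (0.224), and MHC and interferon-response genes higher in 7 of 21 and pancreas genes lower in 4 of 6 (both 0.268). Camera did not call fatty acid oxidation genes (4 of 6 higher), cholesterol synthesis genes (1 higher and 1 lower of 5), heat-shock and ER-stress genes (2 higher and 1 lower of 9) or lymphocyte markers (1 of 7 higher). Nor did it call the clock genes, the macrophage and the endothelial markers, whose 9, 5 and 5 members stayed under the size threshold. Lists too short to test held Uty as the only higher gene among 2 Y-linked genes and neither of 2 X-linked genes past the threshold. They also held 1 higher gene and Scd2 as the lower gene among 4 fatty acid synthesis genes (median 0.48, mean -0.36), and none of 3 bile duct markers past the threshold. All these counts were the same when adjusted over the list alone.

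In all, limma called 3055 features, 1034 higher and 2021 lower in liver, 858 of them named. The embryo mix was a single reference, so the errors are those of liver across strains, and the direction of all ratios is the likely one given above.

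Cyp2b9, a P450 gene of steroid and drug oxidation, was 4.55-fold higher in female than in male liver (log2 2.19 ± 0.51 SD of the strain differences, n = 17 strains, limma adjusted p = 3.79e-10). The related Cyp2b13 was 4.44-fold higher (2.15 ± 0.52, limma adjusted p = 5.79e-10), and both had this direction in 17 of 17 strains. Males had 5.71-fold more of Cyp7b1, an oxysterol hydroxylase of bile acid synthesis (log2 -2.51 ± 0.78, female over male), and 5.16-fold more of Elovl3, which elongates fatty acids (-2.37 ± 0.94), both in 17 of 17 strains (limma adjusted p = 2.37e-08 and 9.88e-07).

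**Figure D1:**
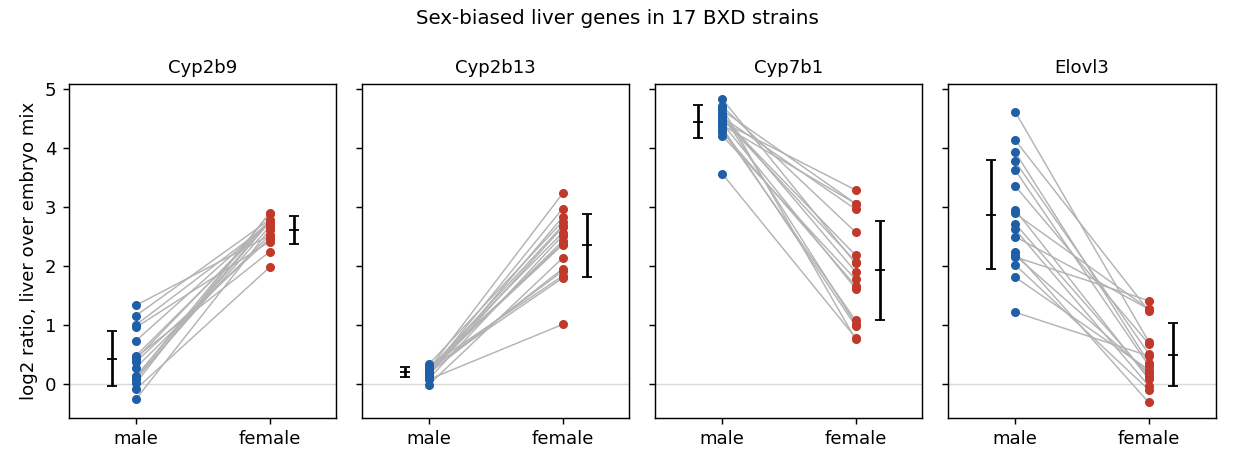
Log2 ratio of liver over embryo mix in males and females of 17 BXD strains for Cyp2b9, Cyp2b13, Cyp7b1 and Elovl3. Each line joins the sexes of a strain, and bars give mean and SD; Cyp2b9 averaged 2.61 in females and 0.42 in males, Cyp7b1 1.92 and 4.44.

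The interferon-induced GTPases Gbp3 (1.24 ± 0.61, 16 of 17 strains) and Tgtp1 (1.23 ± 0.93, 17 of 17) were also higher in females, as were the stress gene Gadd45b (1.17 ± 0.72), the mitochondrial pyruvate carrier subunit Mpc1 (1.01 ± 0.56) and the granule proteoglycan Srgn (0.92 ± 0.59). Further such genes were Cetn3 (0.87 ± 0.62), Atpif1, an inhibitor of the mitochondrial ATP synthase (0.87 ± 0.53), and the drug efflux pump Abcb1a (0.86 ± 0.41). Lower in females were Moxd1 (-1.45 ± 1.26), Kcnip3 (-0.94 ± 0.70), the P450 genes Cyp2d9 (-0.93 ± 0.57) and Cyp2d22 (-0.78 ± 0.34), the arginine methyltransferase Carm1 (-0.82 ± 0.58) and the transcription factor Irf2 (-0.78 ± 0.30). So were Syn1 (-0.74 ± 0.45), the efflux pump Abcg2 (-0.71 ± 0.46), Krt6b (-0.71 ± 0.44) and the casein gene Csn1s1 (-0.69 ± 0.62).

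On average over strains, genes of the sex chromosomes followed the labels of the BXD arrays. Both measured Y-linked genes were lower in females, Eif2s3y at -0.73 ± 0.42 in 15 of 17 strains and Uty at -0.70 ± 0.74 in 14 of 17. Both measured genes that escape X inactivation were higher, Eif2s3x at 0.84 ± 0.40 and Ddx3x at 0.73 ± 0.48 in 17 of 17. In BXD27 both Y-linked genes read higher in the female (Eif2s3y 0.10, Uty 0.38). So did Eif2s3y in BXD8 (0.12) and Uty in BXD18 (0.007) and BXD28 (0.54). Against the embryo mix Uty averaged 0.68 in females and 1.38 in males. Of 7 male-biased liver genes 6 were lower in females, including Cyp2f2 (-0.57) and the growth factor receptor Egfr (-0.54), and Cspg5 was not called (camera adjusted p = 7.34e-05). Of 13 female-biased genes 9 were higher, including Cyp2a4 (1.02), Fmo2 (0.92), Cyp2c40 (0.82) and Fmo1 (0.76), while the neurotrophin receptor Ntrk2 was lower (-0.28) and Cux2, Cyp2c39 and Lpl were not called (camera adjusted p = 1.19e-06). These calls held with an estimated correlation (adjusted p = 0.0121 and 6.67e-04), and the counts were the same when adjusted over the list alone.

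Of all 21915 features 7295 were called between the sexes, so calls in part of a list do not by themselves set that list apart. Cell division genes were higher in females in 6 of 13 cases, 7 when adjusted over the list alone, among them Hmgb2 (0.40), Top2a (0.39) and Mcm2 (0.30). Camera called the list (adjusted p = 0.0315), and the call was lost (adjusted p = 0.653 with an estimated correlation). MHC and interferon-response genes were higher in 10 of 21 and lower in 1, with Ifit3 at 0.56, Psmb9, an immunoproteasome subunit, at 0.40 and Irf1 at 0.32 against Ifi202b at -0.60 (camera adjusted p = 0.125). Respiratory chain genes were higher in 6 of 10 (Ndufa2 0.59, Atp5j 0.52; camera adjusted p = 0.126), and ribosomal protein genes in 4 of 9 (Rps3 0.61; 0.126 likewise). Among metabolic lists the calls went both ways: bile acid genes had 3 higher (Nr1h4, the bile acid receptor, 0.34) and 2 lower of 9, with a median of 0.01 against a mean of -0.26. Drug metabolism genes had 4 higher and 3 lower of 18 (Ephx2 -0.31), and fatty acid oxidation genes 3 higher (Pdk4 0.80, Vnn1 0.79) and 1 lower of 6. Hepatocyte genes had 4 higher and 1 lower of 16, and fatty acid synthesis genes 2 lower of 4 (Scd2 -0.38). Apcs, the serum amyloid P gene (0.92), Fgl1 (0.67) and Cp (0.36) were the higher members among 9 acute-phase genes. Clock genes held 1 call in 9 (Per3, -0.23), cholesterol synthesis genes 1 in 5 (Cyp51, 0.45), and embryonic genes 2 in each direction of 15. Heat-shock and ER-stress genes had 2 higher and 1 lower of 9 (Dnaja1 0.58, Hspa1a -0.60; median -0.02, mean 0.02), and Ifi202b was the 1 call among 7 parental variant genes.

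Some markers of other cells were called between the sexes, beside 7295 of all 21915 features. The macrophage complement genes C1qb (0.37) and C1qa (0.33) were higher in females and Cd5l lower (-0.19). Ptprc (0.22) and Cd3e (0.13) of 7 lymphocyte markers, Lrat (0.27) and Lum (0.27) of 6 stellate markers and the endothelial Tek (0.33) were higher. The endothelial Tie1 (-0.28) and Flt4 (-0.12) and the red blood cell gene Rhag (-0.66) were lower; the endothelial list had a median of -0.02 and a mean of 0.02. Of the neighbouring organs, the pancreas gene Reg1 was lower (-0.25; 2 higher and 1 lower of 6 when adjusted over the list alone), and the fat gene Cfd was higher (0.35), a call absent when adjusted over the list alone. Camera called none of these lists (smallest adjusted p among them 0.341, for lymphocyte markers).

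Limma called 7295 features, 3550 higher and 3745 lower in females, 39 of them by at least 1 in absolute log2, and 1251 of them named. Male and female arrays lay mostly in different runs of consecutively deposited arrays, so the sexes were also fitted on 39 values (1 per strain, sex and replicate number) with and without the run as a term. Without it 8280 features were called, with it 4695, and 3625 in both with the same sign; of the 7295 above, 3438 were among the 4695. In the 5 runs that held both sexes Cyp2b9 differed by 1.45 to 2.51 and Cyp7b1 by -3.19 to -2.31. In none of the 13 strains with both orientations did male and female arrays share a run. The runs of those strains therefore set females of some strains against males of others. The other runs with both sexes hold the 4 strains with forward arrays only, so the values below are not separate from them. In the 4 strains with forward arrays only, limma called 0 features (3276 at an unadjusted p under 0.05), while Cyp2b9 differed by 2.04 there and by 2.23 in the other 13 strains, Cyp7b1 by -3.00 and -2.36, and 76.2% of the 8342 features called in the 13 strains had the same sign.

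The largest F value among named genes was that of Plekhb1, which encodes a pleckstrin-homology protein. Its strain means ran from -0.68 in BXD28 up to that of BXD16 (a 6.38-fold range, SD 0.96 across 13 strains against a residual SD of 0.23, limma adjusted p = 4.73e-05). Of these, 7 strains lay at or above 0.81 while the other strains lay at or below -0.04. The peptide transporter Slc15a2 spanned 3.69-fold (SD 0.61, adjusted p = 1.96e-04), with BXD2 highest and BXD11 lowest. Alad, an enzyme of heme synthesis, spanned 6.68-fold, from 0.14 in BXD12 to 2.88 in BXD15, and the immunoproteasome subunit Psmb10 spanned 2.86-fold. Ppargc1a, a coactivator of fasting metabolism and mitochondrial growth, spanned 7.55-fold with BXD32 highest at 1.57 and BXD28 lowest at -1.35.

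**Figure D2:**
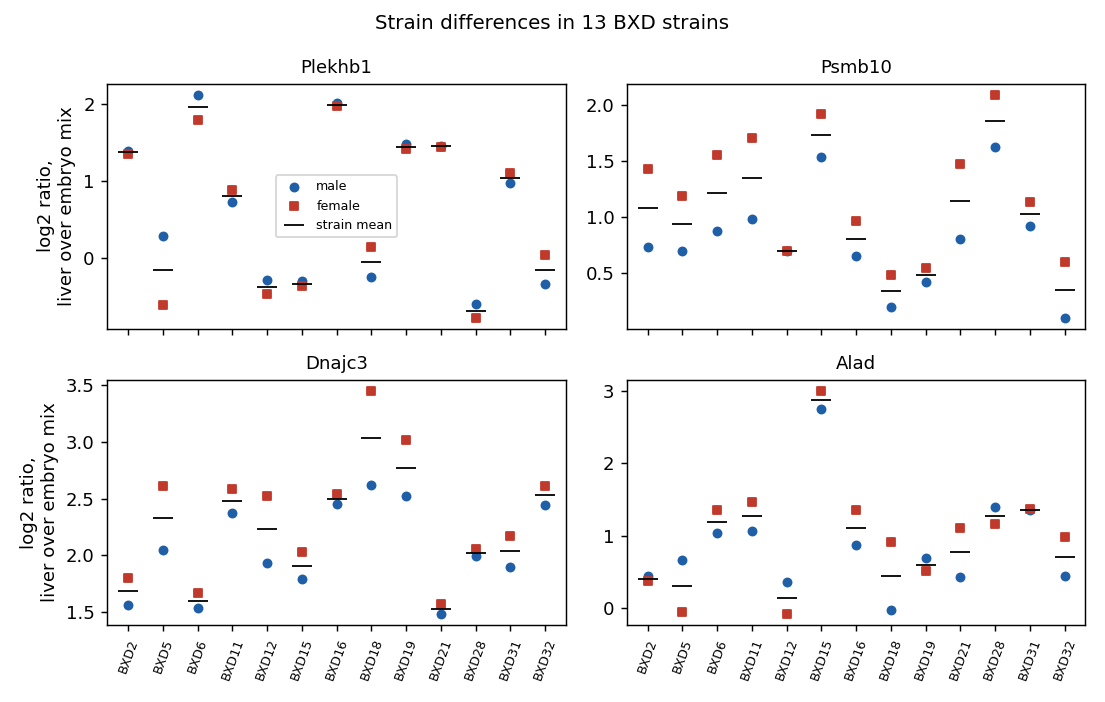
Log2 ratio of liver over embryo mix for Plekhb1, Psmb10, Dnajc3 and Alad in 13 BXD strains. Points are the male and the female value of a strain and dashes the strain mean; for Plekhb1 the strain means span 2.67.

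The other genes with the largest F values were the nucleoside diphosphate kinase Nme1 (SD 0.47), the DNA glycosylase Mpg (0.55), the splicing gene Snrpn (0.30), the proton pump subunit Atp6v1g1 (0.49, lowest in BXD31 at -2.15), the carbonyl reductase Cbr1 (0.42), Ptma (0.30) and Tssc4 (0.24). They also held Banf1 (0.27), the retinoic acid hydroxylase Cyp26a1 (0.64), Vamp5 (0.39), Lsm4 (0.31), Mga (0.44), the lipoprotein lipase gene Lpl (0.67, highest in BXD19 at -0.76) and the ER chaperones Dnajc3 (0.46) and Pdia4 (0.67). Limma's adjusted p for these 20 genes ran from 4.73e-05 to 0.00791.

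Heat-shock and ER-stress genes were called in 4 of 9 cases, Dnajc3, Hsph1, Calr and Pdia4, 5 when adjusted over the list alone (Fisher's exact test, adjusted p = 2.27e-04). MHC and interferon-response genes were called in 3 of 21 (Psmb9, Irf1 and Gbp3), 11 when adjusted over the list alone. Parental variant genes were called in 2 of 7 (Alad and Gbp2b), 3 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0456 for both lists). Fisher's exact test takes genes as independent, and for strain differences no list was tested with an estimated correlation. Female-biased liver genes had 2 calls in 13 (Fmo1 and Lpl), hepatocyte and drug metabolism genes shared a call in Cyp2c29, and acute-phase genes had Apcs (Fisher's exact test, adjusted p = 0.119 or higher). When adjusted over the list alone these lists had 4 of 13, 4 of 16, 8 of 18 and 4 of 9. The other lists tested had no called member in limma, with 3119 of all features at an unadjusted p under 0.05. When adjusted over the list alone, cholesterol synthesis, fatty acid oxidation, bile acid, macrophage, endothelial and pancreas genes had 2 each and male-biased liver genes 1.

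Limma called 265 features, 60 of them named. BXD15 was the highest strain for 75 of the 265 features, where equal shares would give 20.4, and without it the count was 150. The male and the female arrays of each of the 13 strains lay in different deposit runs, and on 31 values (1 per strain, sex and replicate number) limma called 1039 features without the run as a term and 767 with it, 519 in both. Of the 265 above, 228 were among the 767.

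The direct arrays asked which liver genes differ between the parents. Apcs, whose product is a plasma pentraxin, was 8.79-fold lower in B6 than in D2 (log2 -3.14 ± 0.30 SD, n = 4 values, limma adjusted p = 0.00548), and Lpin1, a phosphatidate phosphatase of lipid synthesis, was 4.76-fold higher (2.25 ± 0.21, limma adjusted p = 0.00705). Plekhb1 (1.82 ± 0.28), the purine oxidising enzyme Xdh (1.76 ± 0.43), the aldo-keto reductase Akr1c14 (1.21 ± 0.22), the guanylate kinase Guk1 (0.94 ± 0.15) and Habp4 (0.92 ± 0.11) were higher in B6. The thiopurine methyltransferase Tpmt (-1.34 ± 0.19), the elastase Cela1 (-1.14 ± 0.16), Mpg (-1.03 ± 0.20), the stress transcription factor Atf5 (-1.01 ± 0.14), Ly6e (-0.95 ± 0.07) and Pdia4 (-0.81 ± 0.07) were lower. All 13 had the same sign in 4 of 4 values, with limma adjusted p from 0.00548 to 0.0488.

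**Figure D3:**
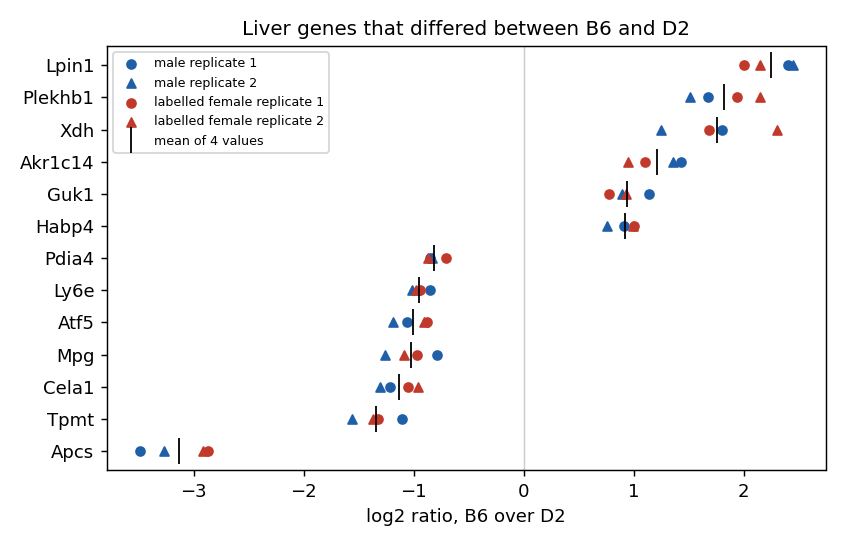
Log2 ratio of B6 over D2 liver for the 13 named genes called by limma, by sex as labelled and replicate number. Points are the 4 values and bars their mean, from -3.14 for Apcs to 2.25 for Lpin1.

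On the arrays labelled female, Y-linked genes and several sex-biased genes had other B6 over D2 values than on the arrays labelled male. In the likely direction of the ratio B6 had the male-type values, and with the ratio turned it would be D2. Eif2s3y and Uty, which are Y-linked, read 0.56 to 1.37 (B6 over D2) on the 3 arrays labelled female and -0.11 to 0.33 on the 3 arrays labelled male. Cyp2b9 averaged -2.69 on the values labelled female and -0.12 on those of males, and Cyp7b1 2.58 and 0.02. Across the 39 features with an absolute log2 sex difference of at least 1 in the BXD strains, the slope of B6 over D2 on that difference was -0.96 and -1.18 for the values labelled female and -0.12 and -0.13 for those of males; the features are not independent replicates.

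**Figure D4:**
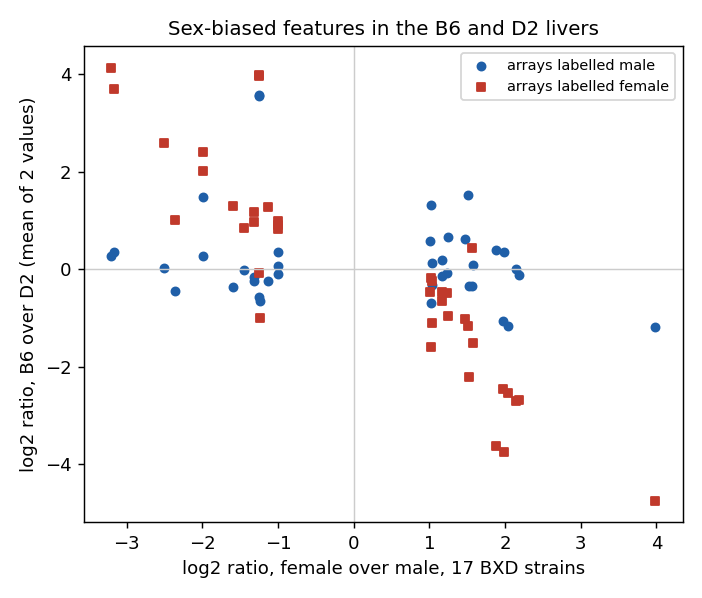
Log2 ratio of B6 over D2 liver against the female over male log2 ratio of the 17 BXD strains, for 39 sex-biased features. Squares are means of 2 values labelled female and follow, with scatter, a line of slope near -1. Circles, means of 2 male values, lie nearer 0 for most features but not all, as for Hpgd (circle 1.31, square -0.17).

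Acute-phase genes were lower in B6 in 1 of 9 cases (Apcs), 5 when adjusted over the list alone. The further genes of that count were not called over all features, among them Fgl1 (-1.45 ± 0.62), Serpina3n (-1.33 ± 0.62) and Lbp (-1.22 ± 0.53). Saa3, which passed neither adjustment, read -3.82 and -3.78 in males and 0.05 and -0.35 in the values labelled female. Camera called the list (adjusted p = 3.78e-06), and the call was lost (adjusted p = 0.801 with an estimated correlation). Adult hepatocyte genes had 7 of 16 lower when adjusted over the list alone, among them Mat1a (-0.47 ± 0.23) and Arg1 (-0.39 ± 0.05), none of which passed the adjustment over all features in limma. Camera called the list (adjusted p = 5.92e-05), again lost (adjusted p = 0.801 with an estimated correlation). Drug metabolism genes had Tpmt as the only call in 18, 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0594). The pancreas list had Cela1, the ER-stress list Pdia4, and the lists of other cell types had no call in limma.

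Limma called 39 features, 20 higher and 19 lower in B6, of which 13 were named, with 2894 at an unadjusted p under 0.05. The calls rest on 4 values, 2 of them from RNA whose sex label is in doubt. Without a value the count was 0 (male replicate 1), 3 (female replicate 1), 2 (male replicate 2) or 29 (female replicate 2). With a dye term it was 0 in limma (570 at an unadjusted p under 0.05). That fit tests the mean of the 2 replicate 1 values, the only ones with both orientations, so fewer values bear on it. Without the values labelled female but with the enriched arrays the count was 141, including 29 of the 39. A sex term on the 4 values called 0 features in limma (1673 at an unadjusted p under 0.05; smallest adjusted p 0.249).

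Part of the genes that differed between the parents also differed among the BXD strains, which share no array with them. Of the 39 parental calls 19 were strain calls, where independence would give 0.472 (Fisher's exact test, odds ratio 83.2, 95% interval 41.6 to 168, p = 1.07e-26), and the named ones were Apcs, Plekhb1, Mpg, Pdia4 and Guk1. That test takes features as independent, while unnamed probes were not merged by gene, so its interval and p likely overstate the precision. The SD of strain means was 0.99 for Apcs and 0.38 for Guk1, and its median was 0.617 over the parental calls against 0.150 over the other features. Across all features, which are not independent replicates, the absolute parental log2 ratio and the strain SD had a Spearman's rho of 0.373. Dim probes were not set apart in any of these comparisons, so how far signal level adds to them was not tested.

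Over the 39 features called between the parents, the male values of a strain matched the female values of the same strain better than those of any other strain in 16 of 17 strains. Over all 21915 features this held in 6 of 17 strains (mean correlation 0.315 within strains; permutation p = 2.1e-04 for the count). The exception over the 39 features was BXD18, whose male values correlated at 0.537 with its own female values and at 0.643 with those of BXD32, across features that are not independent replicates. Over the 39 features the mean correlation was 0.673 within strains and -0.0416 between them (permutation p = 1e-05, the smallest that 100000 permutations can give).

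The enriched arrays, 1 per sex and in 1 orientation, were not tested on their own. Of the 39 features called between the parents, 36 had the same sign on the enriched male array and 37 on the array labelled enriched female. Lpin1 read 2.69 and 1.14 there, Apcs -1.94 and -2.04, and Tpmt -1.57 and -2.24, while Akr1c14, at 1.21 without enrichment, read -0.26 and -0.13.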

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

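The tests on the RNA labelled B6 female and the comparison of 13 with 4 strains in single genes were chosen after the result was seen.

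Among the sex-linked, sex-biased, acute-phase and hepatocyte lists, 8 genes had both B6 over D2 values labelled female on one side of 0 and both male values on the other, which drew attention to them. Genes of other lists had this pattern too and were not followed up. The difference between the values labelled female and the male values was 1.46 for Elovl3, 1.43 for Egfr, -2.40 for Fmo1, -1.12 for Cyp4a14 and -0.38 for Eif2s3x among sex-linked and sex-biased genes, and 1.88 for Orm1, -1.09 for Bhmt and -0.71 for Rgn among acute-phase and hepatocyte genes. Limma's adjusted p for a sex term ran from 0.290 (Orm1) to 0.664 (Eif2s3x) in these genes, so none of the differences passed with 2 values per sex.

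A candidate explanation is that the RNA labelled B6 female came from a male, given the likely direction of the ratio (with the ratio turned, the RNA labelled D2 female). Under it, Y-linked genes should exceed D2 on every array labelled female, and the lowest such value was 0.564, against a highest value of 0.333 on the arrays labelled male. A strain difference in sex-biased genes between females of B6 and D2 is argued against by the same genes, since 6 of 6 Y-linked values labelled female lay above every value labelled male. The enriched array labelled female showed neither, with Eif2s3y at 0.11, Uty at -0.13 and a slope of -0.05 on the BXD sex differences, so the label in doubt may concern only the RNA of the 3 arrays without enrichment. For RNA of a male, genes that escape X inactivation should be lower on the arrays labelled female, and these gave less support. Between values labelled female and male, Eif2s3x differed by -0.38 and Ddx3x by -0.16, against 0.84 and 0.73 (female over male) in the BXD strains. On the 3 arrays labelled female Eif2s3x read -0.44 to 0.17. What the RNA in doubt was stays open, and no biological explanation beyond the strain difference was tested.

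Eif2s3y drew attention because its sex difference was not the same in both sets of strains: it was -0.93 ± 0.20 (SD) in the 13 strains with both orientations and -0.09 ± 0.23 in the 4 with forward arrays only (exact permutation test over 2380 splits, 2-sided, adjusted p = 0.00378 over 9 genes). The 4 strains also differ from the 13 in orientation and deposit run, so an effect of strain cannot be told apart from these. Uty, the other measured Y-linked gene, was -0.65 and -0.87.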

How the results depend on the processing

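Added after seeing the data were the run term, the exchanged arrays, the strains left out together, the dye subtraction and the values labelled female left out.

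Liver against embryo (2899 to 3496 features), the overlap of parental and strain calls (odds ratio 6.52 to 77.0) and strain identity (16 of 17 strains with arrays exchanged, 13 of 13 with both orientations, 6 of 17 over all features, p at most 2.1e-04) stayed past their thresholds under every alternative run on them. The cause of the moves below was not tested except where noted. Female against male gave 6543 to 8069 features with a strain left out, 5478 without the strain block that pairs the sexes, 4695 with the run as a term (39 values, 8280 on them without it), and 0 in 4 strains (3276 unadjusted), where fewer samples were used. Strain differences gave 3373 features in 17 strains after a dye correction, 5642 as they are, where the dye effect adds to strain by construction, 147 on forward and 101 on swapped arrays, 767 with the run as a term (31 values, 1039 on them without it), and 150 to 286 with a strain left out, 150 without BXD15.

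B6 against D2 gave 77 features after scaling (22 of the 39 among them), 34 after quantile normalization (14 of the 39), 0 with trend and robust settings (746 unadjusted), 0 with a dye term (570), 0 in males (1261) and 0 in values labelled female (2527), where fewer values were used, 232 with 6 arrays as separate values, 510 with the enriched arrays, 70 with the dye effect subtracted, and 141 with values labelled female left out and enriched arrays added. With a value left out it gave 0 to 29 (0 without male replicate 1, 2 without male replicate 2, 3 without female replicate 1). The fit with a dye term tests the mean of the 2 replicate 1 values, so fewer values bear on its count too. Replicate number as a block gave 9; the replicates share only a number, and the deviations of replicate 1 correlated at 0.325 between sexes and at 0.586 with the dye effect across features, since replicate 2 has swapped arrays only.

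Gene lists past camera numbered 16 in liver against embryo, 3 with an estimated correlation and 23 by fry, which tests direction on balance. They numbered 3 for sex (9 by fry) and 2 for B6 against D2 (0 with an estimated correlation, 0 by fry). Over named genes and alternatives, calls kept and lost numbered 717 and 27 for sex, 500 and 20 for strains, and 90 and 131 for B6 against D2, with 0 reversed; in liver against embryo 16 values moved on the B6 male arrays and none was lost. With no missing value, the filter on complete features changed nothing. Dim probes were not set apart.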

Other observations

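The tests on exchanged arrays were chosen after the result was seen.

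Other strain patterns appeared among the named genes. BXD15 and BXD28 were the highest strains for Nme1 (0.88 and 0.80), Banf1 (-0.75 and -0.88), Vamp5 (0.97 and 0.91) and Mpg (0.65 and 0.58), while BXD12 was the lowest strain for 42 of the 265 called features, BXD32 for 39 and BXD21 for 35, against 20.4 by equal shares. Mga, a partner of Max, was highest in BXD31 (-0.73), BXD2 (-0.97) and BXD5 (-1.12) and was lowest in BXD11 (-2.04). B6 males on the embryo mix read 0.26 for Cyp2b9, close to BXD males (0.42 ± 0.46 SD), and 0.77 for Elovl3, below BXD males (2.86 ± 0.92).

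Genes linked on a chromosome carry the same parental haplotype in most strains. The hypothesis that neighbours vary together was tested on the 300 named genes with the largest F between strains. The 436 pairs within 10 Mb had a mean absolute correlation of 0.369 across 13 strains, against 0.329 for pairs on different chromosomes and a 95th percentile of 0.348 in 1000 shuffles of positions (shuffle p = 0.00200). The strongest pairs were Pdss1 and Trdmt1, Gamt and Gstt1 (0.890) and Phlda3 and Ctse (-0.878), which are not of one gene family. Their parental log2 ratios were small: -0.06 and -0.15, -0.09 and 0.002, and -0.05 and -0.44. These pairs therefore do not by themselves point to a difference between the parental alleles. Other pairs, such as Tap1 and Tap2 (0.849), C1qa and C1qb (0.820) and Ifit2 and Ifit3 (0.804), are related or share regulation, so shared haplotypes may be only part of the pattern. Cross-hybridisation of related probes was not tested. In 11 of 15 linked pairs whose parental ratios both exceeded 0.5 in size, the sign of the correlation was that of the product of the parental ratios.

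The swapped arrays labelled BXD6 female replicate 1 and BXD21 female replicate 2 may have been exchanged. Over 250 genes picked without these strains, they correlated at -0.163 and -0.125 with the forward array of their own label and at 0.798 and 0.878 with that of the other. Noisy hybridisation is argued against by the smaller of the latter, 0.798, which exceeds the lowest own correlation of the other 29 dye pairs, 0.527. With the pair exchanged, limma called 383 features between strains, 7487 between sexes and 3038 between liver and embryo. No biological explanation was tested.

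For the large number of sex differences, of 100 assignments of sex within strains 1 gave as many calls as the real one, which was that one itself (7295, with 1949 as the highest other). That argues against chance as the source of the count, and 1 in 100 is the smallest share such a test can give. In the 13 strains whose sexes share no run, exchanging the sexes also exchanges the runs, so this cannot tell sex from run. Of the 7295 calls 47.1% were also called in a fit on 39 values with the run as a term, and on those same values 43.8% of the 8280 calls without the term stayed with it. For the 20 called genes of the sex lists, 100% kept their sign in the mean within-run difference and 15 of 20 in each of 5 runs. Over all 7295 calls 99.0% kept their sign on the first measure. The arrays within runs also made the calls, so keeping a sign is largely built in and cannot tell runs from sex. It says nothing of size either. For Cyp2b9 and Cyp7b1 the differences within each run (1.45 to 2.51 and -3.19 to -2.31) argue against runs as the whole source for these genes. In the 4 strains with forward arrays only, 76.2% of the 8342 features called in the other 13 strains had the same sign. Those 4 strains took no part in these 8342 calls, and features are not independent replicates. How many calls runs added, and how many are a difference between the sexes, stays open.

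For strain differences, 1 of 100 assignments of strains within females gave as many calls as the real one, the real one itself (265, with 5 as the highest other). That argues against chance as the source of the count, and 1 in 100 is again the smallest share possible. With a strain left out the count fell at most by a factor of 1.77, to 150 without BXD15, so no single strain gave all the calls. Such counts cannot tell an effect of the arrays of BXD15 from a trait of its mice.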
